A study of Mus musculus with 2 samples.

How the data were processed

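Total RNA isolated with Trizol was made into libraries with a NEBNext Ultra kit. Whether poly(A) transcripts were selected is not given in the sources used here. Bone marrow monocytes of wild-type C57BL/6 mice aged 6 weeks gave 1 library, and macrophages that had differentiated from such monocytes in the presence of lysophosphatidic acid (LPA, a bioactive phospholipid that acts through cell surface receptors) gave the other. Each library was assigned to its group from its title. Whether the monocytes and the macrophages came from the same animals, how the monocytes were isolated and how long the cells were cultured are not given in the sources used here.

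The authors deposited 1 table of 47643 genes. Per the file headers it holds, for each library, counts of reads mapped to a gene, to its exons and to its introns, and the counts used here are those the authors classed as unique. RPKM values were deposited beside them, and they equal the exon reads divided by the exon length and by 1 total per library, with 0 genes off by more than 1%. The deposited normalized signal has the same set of sorted values in both libraries, which is what quantile normalization gives. Per the file headers, the authors' fold change is the ratio of these normalized values, written with a minus sign where the monocyte value is higher (a signed score), and their FDR-corrected p-value comes from Baggerley's test on 1 library against 1. Per the file headers, the exon length is given in bases. The mapper, its version and its settings are not given in the sources used here. Per the submitters' processing notes the genome build was mm9. The coordinates in the deposited table are those of the later build GRCm38 instead: 47224 of the gene identifiers were found in GENCODE M21, which is on GRCm38, and 40773 of them (86.3%) had exactly the same chromosome, start and end. Coordinates are given 1-based on GRCm38.

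These steps of the authors bear on the values. Reads that mapped to several places were nearly all left out, since reads not classed as unique made up 0.0578% of gene reads in the monocyte library and 0.0596% in the macrophage library. Genes with near-identical copies (Ly6c2 and Ly6c1, the globin and H2 genes, ribosomal protein genes, Gapdh, the ferritin genes and several mitochondrial genes with nuclear copies) are therefore undercounted, and their levels are uncertain. Whether strand was used in counting is not given in the sources used here, so antisense and overlapping genes are uncertain too. An exon length of 0 was listed for 16517 genes, 41 of them protein-coding, and these have no exon reads.

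Unique exon reads were chosen as the measurement once the table had been seen, because gene reads include introns. They were converted to CPM, scaled by the sum of the library's exon reads, 12473180 for the monocytes and 16726342 for the macrophages. A gene entered when it reached 5 CPM in at least 1 library, which is 62.4 reads in the monocyte and 83.6 reads in the macrophage library. The log2 ratio is log2(CPM + 1) of macrophages minus that of monocytes, and a gene was counted as higher or lower at a ratio of 2-fold on that scale. Folds of named genes are plain CPM ratios with an exact (Clopper-Pearson, conditional on the sum) 95% interval. A gene with no read in 1 library is given a lower bound of its fold, computed against 3 reads in that library (0.241 CPM in monocytes, 0.179 CPM in macrophages). That floor is a one-sided limit of a count of 0, so the interval of such a gene starts lower. With 1 library per group there is no replicate check of any difference, no test was made and no p-value was computed. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

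Before the data were examined, 34 gene lists were fixed. A list is described by the median log2 ratio of its members past the floor (at least 4 were needed) and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. A list is said to stand apart below percentile 1 or above percentile 99, as a description of these libraries. Genes are named by a rule fixed at the same time: from each list up to 4 members with the largest absolute log2 ratio, and for lists of other cell types also the 3 with the highest level; Adgre1, Csf1r, Cd68, Ly6c2, Ccr2, Pparg, Lpar1 to Lpar6, Akt1 and Mtor whatever their values; the 10 genes with the largest and the 10 with the smallest log2 ratio among genes at 50.0 CPM or more, leaving out predicted genes, RIKEN clones, pseudogenes, immunoglobulin genes (constant regions included), T cell receptor segments and small RNAs; and the 5 highest genes of each library. Some members of lists were left out for length, and list members outside the rule that serve as exceptions or level comparisons were chosen after their values were seen. Itgam, which the rule also names, is not analysed here.

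The alternatives fixed beforehand were other pseudocounts (0.1 and 5), no floor and a floor of 25 CPM, centring on the median or the trimmed mean ratio, totals without the top 20 genes, the authors' deposited fold change, a 4-fold limit, the mean in place of the list median, and matching random lists on the monocyte level. Unique gene reads, RPKM (floor 1, pseudocount 1) and protein-coding genes without ribosomal, mitochondrial and immunoglobulin genes were added after the data had been seen. The steps were tested on simulated counts for the comparison of macrophages with monocytes over 10051 genes: 100.0% of the 100 genes made 4-fold higher and 100.0% of the 100 genes made 4-fold lower came out past 2-fold, 0.5% of lists of unchanged genes fell outside percentiles 1 to 99, and 94.6% of intervals held the true ratio. Apart from the changed genes, the simulated libraries differed by counting noise alone, drawn for each gene independently. The 0.5% therefore does not tell how often a list of genes that vary together would stand apart in the real libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.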

Results

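The transcriptomes of mouse bone marrow monocytes and of macrophages derived from bone marrow monocytes with LPA were compared by RNA sequencing, with 1 library per group. The comparison asks how gene expression differs between the monocytes and the macrophages that LPA gives rise to. Neither library is from a culture without LPA. An effect of LPA itself therefore cannot be told apart from that of culture or of differentiation. The monocyte library held 12473180 and the macrophage library 16726342 unique exon reads, and levels are given as CPM, the count scaled by this total. The number of genes at 5 CPM or more was 9694 in monocytes and 9727 in macrophages, and 10407 genes reached that level in at least 1 of the libraries. Values below are from single libraries.

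Genes of macrophages, lipid uptake and lysosomes were far higher in the LPA-derived macrophages, and genes of classical monocytes and cell division were far lower. Of the 10407 genes, 1440 (13.8%) were at least 2-fold higher in the macrophages, 2073 (19.9%) were at least 2-fold lower and 6894 (66.2%) lay within 2-fold. At 4-fold the counts were 616 higher and 697 lower. The largest ratios in favour of macrophages among genes at 50.0 CPM or more belonged to Mmp12 (macrophage elastase), Gpnmb, Anpep, Cd36, Ahnak2, Stab1, C3ar1, Rnf128, Atp6v0d2 and Mamdc2. Leaving out immunoglobulin genes, the largest in favour of monocytes belonged to Nr4a1, Ctsg, Mpo, Prtn3, Plac8, Nr4a2, F13a1, Fcnb, Elane and Ms4a3. Across genes, log2(CPM + 1) in the libraries correlated with Pearson's r = 0.74 and Spearman's rho = 0.78, over genes that are not independent replicates.

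The macrophage library was the more concentrated one. Its 5 highest genes, Psap (17763 CPM), Gpnmb (15918 CPM), Ctsb (15491 CPM), Apoe (14982 CPM) and Ctsd (14040 CPM), took 7.82% of exon reads, whereas the 5 highest genes of the monocyte library, Lyz2 (8774 CPM), Eef1a1 (7638 CPM), Actb (5925 CPM), Mpo (5904 CPM) and Psap (5827 CPM), took 3.41%. The median log2 ratio of all genes was -0.23, so the balance of higher and lower genes depended on scaling: 41.0% of the genes past 2-fold were higher in macrophages, against 54.3% after centring on that median, 53.6% after centring on the trimmed mean, 50.4% when the top 20 genes were left out of the totals and 50.0% with the fold change in the authors' deposited table. Lyz2 was 1.37-fold and Actb 1.06-fold higher in the macrophages, and both were lower there by the authors' deposited fold change. In the authors' deposited table, a total of 10915 genes have an FDR-corrected p below 0.05, 5269 higher and 5646 lower in macrophages. They include 80.8% of the genes past the floor, and that test compares these libraries, not the conditions.

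**Figure D1:**
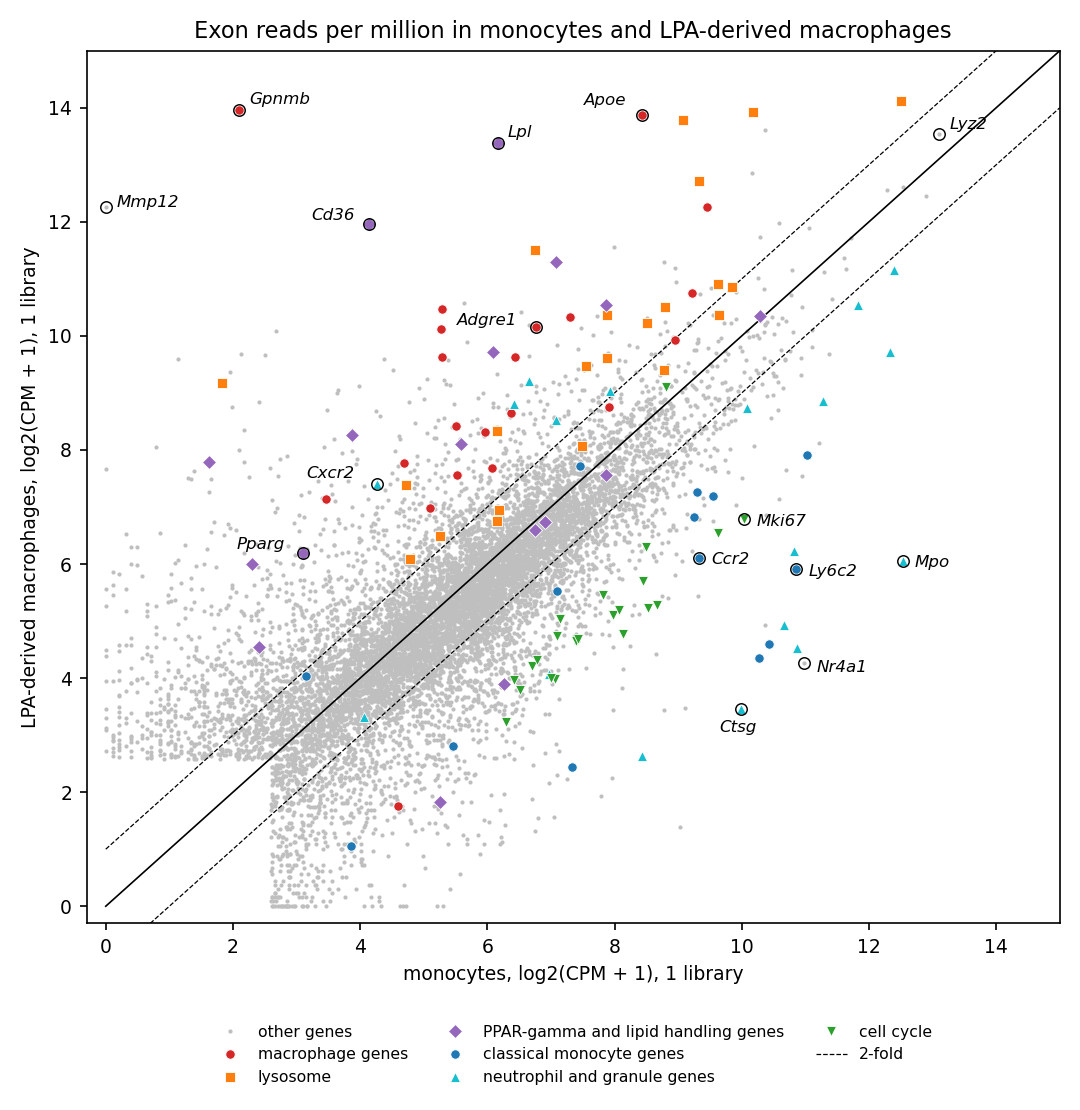
Expression in monocytes (horizontal axis) and LPA-derived macrophages (vertical axis) as log2(CPM + 1), 1 library each, for the 10407 genes at 5 CPM or more in at least 1 library. Points are genes, coloured by list, the solid line marks equal levels and the dashed lines 2-fold. Gpnmb, Mmp12, Lpl and Cd36 sit far above the lines, and Mpo, Ctsg, Nr4a1 and Ly6c2 far below.

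Of 21 macrophage genes past the floor, 18 were at least 2-fold higher in the macrophage library and 1 was lower (median log2 ratio 2.91, percentile 100 of random lists). Adgre1, which encodes F4/80 (chromosome 17, 57358686 to 57483529), stood at 107.3 CPM in monocytes and 1138 CPM in macrophages, a 10.6-fold difference (95% counting interval 10.04 to 11.2). Cd68 was 8.24-fold higher (7.87 to 8.64) and Csf1r, the receptor of macrophage colony-stimulating factor, 2.92-fold higher (2.85 to 2.997). Gpnmb, a transmembrane glycoprotein of phagocytes (chromosome 6, 49036546 to 49070929), went from 41 reads in monocytes to 266245 reads in macrophages, 4842-fold (3570 to 6748), or 1296-fold in the authors' deposited table. Apoe was 43.3-fold, Trem2 37.2-fold and C1qb 29.7-fold higher. The exception was Cd163, a haemoglobin scavenger receptor, at 23.1 CPM in monocytes and 2.39 CPM in macrophages.

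Genes of lipid uptake and of the PPAR-gamma programme were also higher as a group, with 11 of 17 at least 2-fold higher and 2 lower (median 2.68, percentile 100). Pparg itself (chromosome 6, 115360951 to 115490399) was 9.44-fold higher (7.66 to 11.8), at 7.62 CPM in monocytes and 71.9 CPM in macrophages. Lpl, the lipoprotein lipase, stood at 70.6 and 10679 CPM, a 151-fold difference (142 to 162). The fatty acid transporter gene Cd36 was 238-fold higher, the fatty acid binding protein gene Fabp4 106-fold and the cholesterol exporter gene Abca1 22.4-fold. Olr1, another scavenger receptor gene, was 14.5-fold lower and Dgat2, a gene of triglyceride synthesis, 5.45-fold lower. Of 16 cholesterol synthesis genes, 13 lay within 2-fold and 3 were higher, Lss, Hmgcs1 and Sqle (median 0.17, percentile 94.9).

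Lysosomal genes were higher as a group: 17 of 22 passed 2-fold and none was lower by 2-fold (median 1.71, percentile 100). The cathepsin genes Ctsl, Ctsd and Ctsb were 27.3-fold (25.8 to 28.8), 26.1-fold (25.5 to 26.8) and 13.5-fold (13.2 to 13.7) higher. Psap, the prosaposin gene, was 3.05-fold higher from an already high monocyte level, but 1.32-fold by the authors' deposited fold change. Atp6v0d2, a proton pump subunit that the osteoclast list also holds, went from 2.57 to 576.5 CPM. Mitf and Tfeb, which encode regulators of lysosomal genes, stood at 25.5 and 71.4 CPM in monocytes and at 166.8 and 122.6 CPM in macrophages. In the osteoclast list, 6 of 7 genes were higher (median 1.43, percentile 99.97), among them Dcstamp (38.2-fold), Tnfrsf11a, the gene of the RANK receptor (11.2-fold), and Itgb3 (2.73-fold), while Nfatc1 stood at 94.4 and 68.5 CPM. The osteoclast call was lost when random lists were matched on the monocyte level.

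Matrix and adhesion genes were higher in 14 of 19 cases and lower in 3 (median 2.93, percentile 100). Mmp12 (chromosome 9, 7344381 to 7369499) had 0 reads in monocytes and 82211 in macrophages, at least 20435-fold higher against a floor of 3 reads (the 95% counting interval starts at 16619). Spp1, the osteopontin gene, was 31.3-fold, the urokinase gene Plau 18.6-fold and Itgb5 14.4-fold higher, while Fn1, the fibronectin gene, was 8.50-fold lower and Tgfbi 2.71-fold lower. Oxidative stress response genes were higher in 7 of 10 cases (median 1.41, percentile 99.96), with Srxn1 at 27.0-fold, Prdx1 at 11.9-fold, Gclm at 4.14-fold and Hmox1 at 4.11-fold. Growth factor and receptor genes were higher in 5 of 11 cases and lower in 1 (median 0.84, percentile 99.75). Igf1 was 175-fold (135 to 230.4), Pdgfb 33.6-fold and Pdgfa 30.3-fold higher, and Osm was 5.70-fold lower. MHC class II genes went both ways, with 5 of 9 higher and 2 lower (median 1.13, percentile 99.2): Cd74 was 3.09-fold and H2-Ab1 2.41-fold higher and H2-Ob was 4.85-fold lower. The MHC class II call was lost under several alternatives, with the mean of the list at percentile 84.4.

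Classical monocyte genes were lower in the macrophages in 12 of 14 cases and higher by 2-fold in none (median -2.73, percentile 0.0). Ly6c2 (chromosome 15, 75108158 to 75111970), whose reads are partly shared with Ly6c1, stood at 1849 CPM in monocytes and 59.1 CPM in macrophages, 31.3-fold lower (29.4 to 33.4). Ccr2, the receptor with which monocytes leave the marrow, was 9.48-fold lower (8.91 to 10.1). Plac8 was 63.5-fold, F13a1 58.9-fold and Ms4a4c 36.3-fold lower. Mgst1 (175.3 and 209.7 CPM) and Ly6a (7.86 and 15.4 CPM) were the members within 2-fold.

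Cell cycle genes were lower in 21 of 22 cases (median -2.74, percentile 0.0). Mcm5 and Kif11 were both 10.7-fold, Mcm7 10.1-fold and the proliferation marker gene Mki67 9.62-fold lower, the last at 1048 CPM in monocytes and 109.0 CPM in macrophages. Pcna, a replication and repair factor, stood at 449.0 and 548.5 CPM and was the exception. Of 9 stem and progenitor genes, 5 were lower and none was higher by 2-fold (median -1.17, percentile 1.07). Myb was 25.5-fold, Cd34 15.1-fold and Kit 7.97-fold lower. Markers of some other marrow cells were lower too: erythroid genes in 8 of 9 cases (median -3.14, percentile 0.0, a call lost with the authors' deposited fold change, which only 5 members have), and those of mast cells, basophils and eosinophils in 4 of 7 (median -1.45, percentile 0.21).

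Neutrophil and granule genes went both ways, with 12 of 18 lower and 5 higher (median -1.89, percentile 0.0). Most of the lowest members encode proteins of primary granules, which are made in promyelocytes and in monocyte progenitors, a grouping made after the values were seen: Ctsg was 100.5-fold (86.3 to 117.7), Mpo 90.4-fold (85.2 to 96.1) and Prtn3 83.9-fold (75.7 to 93.2) lower, Mpo (chromosome 11, 87793581 to 87804413) with 5904 CPM in monocytes and 65.3 CPM in macrophages. Elane was 55.1-fold and Fcnb 66.2-fold lower. The secondary granule gene Ngp was 6.13-fold lower but kept 843.6 CPM in the macrophage library, and S100a9 was 2.38-fold lower with 2268 CPM. The authors' deposited fold changes, signed minus for lower, were larger for Mpo, Ngp and S100a9, at -156.4, -10.3 and -4.52. Cxcr2, a receptor gene of mature neutrophils, was 9.16-fold higher (8.005 to 10.5), and Mmp9, Mmp8, Retnlg and Csf3r were 5.91-fold, 5.29-fold, 2.74-fold and 2.13-fold higher.

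Immediate early genes were lower in 12 of 16 cases and higher in 1 (median -1.35, percentile 0.02). Nr4a1, which encodes a nuclear receptor needed by patrolling monocytes, was 112-fold lower (99.6 to 125), the related Nr4a2, outside the list, 77.9-fold, Klf4 44.7-fold, Fosb 10.7-fold and Klf2 6.98-fold lower. Fos stood at 998.4 and 899.2 CPM, and Dusp1 was 2.16-fold higher. Heat shock genes were lower in 4 of 7 cases (median -1.43, percentile 0.20), with Hspa1b at 32.6-fold and Hspa1a at 18.8-fold, a pair of near-identical genes. Genes of the unfolded protein and amino acid stress response were lower in 6 of 12 cases (median -0.97, percentile 0.78), among them Phgdh, Herpud1, Atf4 and Ddit3.

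Interferon-stimulated genes were lower in 9 of 15 cases and higher in none (median -1.63, percentile 0.0). Mx1 was 7.78-fold, Usp18 6.47-fold, Cmpk2 6.19-fold and Irf7 4.52-fold lower. Of 12 genes of classical inflammatory activation, 8 were lower (5 after centring) and 1 was higher (median -1.19, percentile 0.96). The costimulatory gene Cd86 was 13.7-fold lower (authors' deposited fold change -26.4), Cxcl10 21.5-fold (10.1 to 54.6) and Il12a 12.7-fold (6.80 to 26.2) lower from few reads, and Ccl5 5.41-fold higher. Nos2 and Arg1, genes often used to tell activation states apart, were both under the floor in both libraries. The list of alternative activation was split, with 4 of 8 lower (Chil3, Mgl2, Irf4 and Cd163) and 2 higher (Egr2 and the mannose receptor gene Mrc1). Its median was -1.76 (percentile 0.02) and its mean -0.98 (percentile 2.66), and the median depended strongly on the floor. Chemokine and receptor genes also went both ways, with 7 of 15 lower and 4 higher (median -0.70, percentile 3.57), and Ccl2 was 22.8-fold lower. The calls of the inflammatory, alternative activation, heat shock and stress lists were each lost under some alternative.

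Ribosomal protein genes were lower together. Of 78, none was at least 2-fold higher and 44 were at least 2-fold lower, with a median of -1.06 (percentile 0.0), or -0.82 relative to the median of all genes. After centring on that median 13 of the 78 were lower by 2-fold. Rpl23a was 3.49-fold, Rpl13a 2.97-fold, Rpsa 2.88-fold and Rpl35a 2.63-fold lower, and the translation elongation factor gene Eef1a1, outside the list, 1.36-fold lower (authors' deposited fold change -2.95). Nuclear genes of oxidative phosphorylation were slightly lower (median -0.56, -0.32 relative to all genes, percentile 0.29), with 5 of 75 past 2-fold, among them Cox6b2 and Ndufb11, and 1 of 75 after centring. That call was lost with the authors' deposited fold change, with gene reads and with matching on the monocyte level. Of 10 mitochondrially encoded genes 9 lay within 2-fold, and mt-Atp8 was 2.03-fold lower, a difference under 2-fold after centring (median 0.05, percentile 75.04).

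Exon reads counted for the LPA receptor genes were few in both libraries. Lpar5 stood at 4.73 CPM in monocytes and 10.6 CPM in macrophages, 2.25-fold higher (1.67 to 3.07), and Lpar2 at 12.7 and 6.16 CPM, 2.07-fold lower (1.61 to 2.68). Lpar1 (4 and 28 reads), Lpar3 (0 and 3 reads), Lpar4 (15 and 1 reads) and Lpar6 (0 and 0 reads) were under the floor. Since the counting of overlapping genes is uncertain here, a count of 0 does not show that a gene was silent. Of the genes of LPA metabolism and related receptors, Plpp3, a phosphatase that degrades LPA, was 10.3-fold higher (6.37 to 17.6) and P2ry10 7.70-fold lower (5.36 to 11.4). The median of the 5 members past the floor was 0.44 (percentile 77.3). Genes of the Akt and mTOR pathway were alike in both libraries, with 23 of 24 within 2-fold, or 21 after centring, where 3 were higher (median -0.09, 0.15 relative to all genes, percentile 83.4). Akt1 stood at 262.4 and 317.8 CPM and Mtor at 60.3 and 47.1 CPM, and Pik3r5, a regulatory subunit of PI3 kinase gamma, was 2.83-fold higher. All 16 glycolysis genes lay within 2-fold by log2(CPM + 1), and 15 after centring (median -0.16, 0.07 relative to all genes, percentile 65.3), Pfkfb3 being the furthest apart at 130.2 and 65.0 CPM. In the list of SRF and YAP targets, 5 of 13 were higher, led by Ctgf (18.3-fold), Acta2 (11.3-fold), Tagln (8.02-fold, 3.47-fold in the authors' deposited table) and Tpm1 (4.501-fold), and 3 were lower (median 0.08, percentile 80.3). That median was -0.47 with the authors' deposited fold change and -0.31 at a floor of 25 CPM.

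Markers of other marrow cells did not all lie on the same side. Among erythroid genes, Slc4a1, Hbb-bs and Car1 had 482, 447 and 305 reads in monocytes and 0 in macrophages, at least 215-fold, 199.8-fold and 136-fold lower against a floor of 3 reads (95% counting intervals from 174.5, 161.8 and 110.2). The eosinophil granule genes Prg2 and Epx stood at 1662 and 438.5 CPM in monocytes and were 8.28-fold and 44.2-fold lower, whereas the basophil gene Prss34 stood at 158.0 and 107.7 CPM. Of 5 B lineage genes past the floor, 3 were lower, led by Dntt (318 and 0 reads, at least 142-fold against 3 reads, interval from 114.9), and Cd22 was 9.17-fold higher (median -1.92, percentile 5.82). Of 8 dendritic cell genes, 4 were lower, including Flt3 (40.2-fold) and Siglech (131 and 1 reads, 176-fold, 31.0 to 6991), and Itgax, which macrophages also express, was 37.6-fold higher (median -1.04, percentile 1.88). The T and NK cell list had 2 members past the floor, too few to describe, Nkg7 (106.9 and 1.49 CPM) and Cd4 (5.13 and 18.2 CPM). Of 10 stromal and endothelial genes 4 were lower and 3 higher (median -0.41, percentile 28.6), but only 1 was lower after centring or without the top 20 genes: Col1a1 and Col1a2 stood at 919.4 and 839.1 CPM in monocytes and at 446.8 and 416.9 CPM in macrophages, while Postn was 115-fold and Col3a1 17.1-fold higher. Megakaryocyte and platelet genes were higher in 6 of 7 cases (median 1.68, percentile 99.77), among them Ppbp (7.51-fold), Vwf (6.62-fold), Pf4 (4.78-fold) and Itga2b (3.26-fold).

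**Figure D2:**
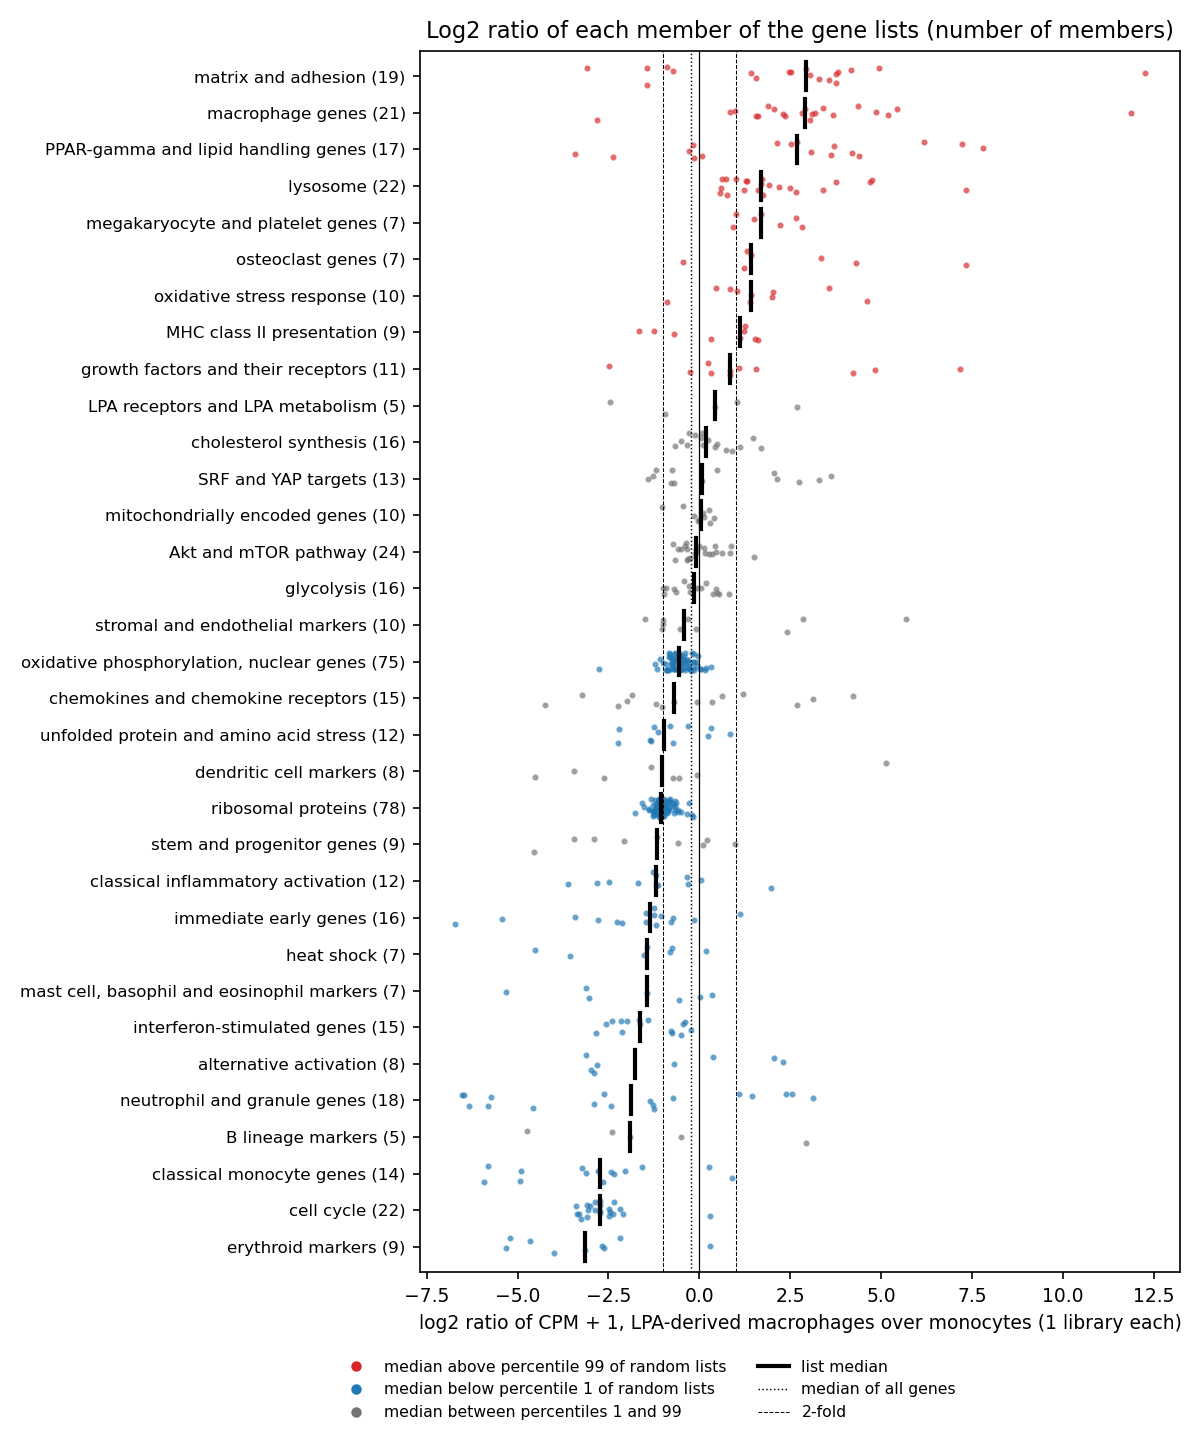
Log2 ratio of CPM + 1 in LPA-derived macrophages over monocytes (horizontal axis, 1 library each) for every member past the floor of the lists with at least 4 such members. Points are genes, thick bars list medians, the dotted line the median of all genes (-0.23) and dashed lines 2-fold. Matrix, macrophage and lipid handling genes lie furthest to the right, with medians of 2.93, 2.91 and 2.68, and erythroid, cell cycle and classical monocyte genes furthest to the left, with medians of -3.14, -2.74 and -2.73.

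In all, 9 lists stood above and 13 below their random lists, 11 lay between, and 1 had too few members. Some lists share members, such as Atp6v0d2 in the lysosome and osteoclast lists and Cd163 in the macrophage and alternative activation lists. The calls are therefore not all separate results. With 1 library per group, the differences contain the cell state, exposure to LPA, the animals, the culture and the library preparation alike. None has a replicate check.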

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

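The test on genomic DNA was chosen only after a first result was seen. Reads outside the exons were not used in the comparison. Intron reads made up 14.15% of gene reads in the monocyte library (2055414 reads) and 9.90% in the macrophage library (1837567 reads). Genes listed without an exon length took 0.240% of gene reads in monocytes (34867 reads) and 0.217% in macrophages (40287 reads), led by the mitochondrial ribosomal RNA genes mt-Rnr2 (10278 and 15499 reads) and mt-Rnr1 (4302 and 8148 reads) and by the predicted gene Gm8995 (6910 and 3598 reads).

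The larger intron share of the monocyte library was set against a pair of technical explanations. Genomic DNA in that library would add intron reads to silent genes as well, but across 14548 genes with at most 3 exon reads in either library, intron reads, as a share of all gene reads, were 0.964 times those of the macrophage library (95% bootstrap interval over genes 0.81 to 1.14), against 1.43 times over all genes. A first test had asked whether the intron read density of silent genes, extended over all introns, came to less than 10% of the monocyte excess of 617284 reads; it came to 10.7%, just above that bound and far from the whole excess. A few abundant spliced transcripts that fill the macrophage library would leave the intron share of single genes as it was. That share was compared over 6419 genes past the floor in both libraries, within 2-fold and with an intron read in at least 1 library. It was higher in monocytes by a median of 2.96 percentage points (quartiles -0.146 and 7.99), and in 73.5% of these genes. Genes without any intron read, whose shares cannot differ, were left out, and both values would be lower with them. More unspliced or nuclear RNA in the monocytes, whether from the cells or from the RNA preparation, stays open and was not tested.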

How the results depend on the processing

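The alternatives on gene reads, RPKM and protein-coding genes were chosen after the data were seen. No list that stood apart reversed under any alternative, and 14 of the 22 lists that stood apart did so under every alternative that gave them a value, among them macrophage, lipid handling, lysosome, matrix, classical monocyte, cell cycle, ribosomal protein, interferon, granule and immediate early genes. Of 424 list values 392 kept their call, 24 lost it and 8 gained it. Of 1567 values of named genes 987 lay within the counting interval of the main value and 580 moved beyond it, with no gene past 2-fold changing sign. Of 140 such genes 13 fell under 2-fold in some alternative. The cause of these changes was not tested, except that a higher floor or fold limit leaves fewer genes.

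At a floor of 25 CPM 880 genes were higher in macrophages, against 1440, and at 4-fold 616 were higher and 697 lower, against 2073 lower in the main comparison. Median centring gave 1806 higher and 1520 lower. Pearson's r across genes was 0.698 with a pseudocount of 0.1, 0.77 with 5, 0.914 with no floor, 0.564 at a floor of 25 CPM, 0.746 with gene reads and 0.788 with RPKM.

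The authors' deposited fold change ended the calls of oxidative phosphorylation (median -0.27), inflammatory activation (-1.04), MHC class II (1.18), the unfolded protein list (-0.70) and erythroid genes (-3.08), and made chemokines (-0.82) and progenitor genes (-1.08) stand below. Matching on the monocyte level ended those of oxidative phosphorylation (-0.56), the unfolded protein list (-0.97) and osteoclast genes (1.43), and added B lineage genes (-1.92). The mean in place of the median ended those of inflammatory (-1.17) and alternative activation (-0.98), MHC class II (0.39) and the unfolded protein list (-0.83), and added progenitor genes (-1.49). A floor of 25 CPM ended those of inflammatory (-1.19) and alternative activation (-0.17) and heat shock (-1.43). Without a floor alternative activation (-0.30) and MHC class II (0.72) lost theirs, and B lineage (-1.24) and progenitor genes (-1.36) gained one. A pseudocount of 0.1 ended that of inflammatory activation (-1.26) and added progenitor genes (-1.33), and one of 5 ended that of MHC class II (0.80) and added dendritic cell genes (-0.93). Gene reads ended those of oxidative phosphorylation (-0.48), MHC class II (0.96) and the unfolded protein list (-0.91), and RPKM those of alternative activation (-0.56) and MHC class II (0.56). Protein-coding genes alone changed no call of the lists they hold.

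Depth limits the low genes: at 5 CPM a gene has 62.4 reads in monocytes and 83.6 in macrophages, and a count of 0 allows up to 3 reads. No paired analysis was possible because each group has 1 library.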

Other observations

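The further gene lists of this part, and the tests on other marrow cells and on a few abundant genes, were chosen only after the main values had been seen; the late neutrophil test and the test of length and GC content were written before their results. Genes of iron handling were higher in the macrophage library in 9 of 12 cases and lower by 2-fold in none (median log2 ratio 1.62, percentile 100 of random lists, 1 gene shared with the earlier lists). The ferritin genes Fth1 and Ftl1 stood at 1320 and 1138 CPM in monocytes and at 12567 and 7454 CPM in macrophages, 9.52-fold and 6.55-fold higher, with reads shared with pseudogenes left out by the authors' counting. The metal transporter gene Slc11a1 was 9.19-fold, Slc11a2 4.44-fold and the iron exporter gene Slc40a1 3.95-fold higher, whereas the transferrin receptor gene Tfrc (145.1 and 116.6 CPM) and Ireb2 (70.6 and 77.8 CPM) lay within 2-fold. A second lysosomal list held 25 genes, coordinated lysosomal genes and targets of the MiT/TFE transcription factors together, and shared no gene with the first. Its genes were higher in 13 cases and lower in 1, or 14 and 0 after centring (median 1.08, percentile 100). They were led by Rragd (12.4-fold), Fnip2 (5.84-fold) and Naglu (5.57-fold).

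Lists of genes named after resident macrophages of single tissues were measured as well, and of the alternatives only median centring was run on these further lists. Their genes are not all restricted to the tissue named, and Marco is in both the alveolar macrophage and the Kupffer cell list. Kupffer cell genes were higher in 4 of 6 cases (median 2.14, percentile 100). The 4 of the 12 listed genes shared with the earlier lists (Vsig4, Timd4, Marco and Cdh5) were all under the floor. Folr2 had 4 reads in monocytes and 1293 in macrophages, and Cd5l was 18.4-fold and Clec1b 6.31-fold higher. The remaining higher gene, Slc40a1, is also in the iron handling list. Id1 was 7.71-fold lower, and Clec4f had 0 reads in both libraries. Alveolar macrophage genes were lower in 4 of 8 cases and higher in 2 (median -1.20, percentile 0.72, 4 genes shared); Chil3, also a monocyte list member, Ear1, Ear2 and Perp were lower and Atp6v0d2 and Abcg1 (5.83-fold) higher. All 7 peritoneal macrophage genes past the floor were lower, 5 of them by 2-fold after centring (median -1.50, percentile 0.90, none shared). Among the members under the floor were Gata6 (0 and 1 reads), Wt1 (0 and 0 reads) and Prg4 (11 and 0 reads). In the alveolar list Car4, Fabp1, Krt79 and Plet1 had 0 reads in both libraries. The medians of these lists therefore rest on their other members. Microglia genes were split with 2 of 6 higher and 2 lower, or 1 lower after centring (median 0.03, percentile 60.9, 3 shared). Plasma cell genes were lower in 6 of 8 cases (median -3.99, percentile 0.0, none shared), with Igha at 520.2 and 1.61 CPM (322-fold lower, and lower by log2 ratio than any gene named above), Ighm at 308.7 and 33.5 CPM and Jchain at 131.6 and 1.97 CPM, while Sdc1 was 19.3-fold higher. Osteoblast genes were lower in 7 of 9 cases, 5 after centring (median -1.65, percentile 0.15, 3 shared), with Bglap at 295 reads in monocytes and 0 in macrophages. Reads of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were 0 in both libraries, and Xist had 767 reads in monocytes and 593 in macrophages.

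Mpo, Ctsg, Prtn3 and Elane, the eosinophil genes Epx and Prg2 and most erythroid and cell cycle genes were higher in the monocyte library. A lower share of monocytes there, with marrow cells of every other type in their place, would raise the markers of those types alike. Of the 6 such lists fixed beforehand 5 had medians below 0, as had the plasma cell and osteoblast lists (-3.99 and -1.65). That of megakaryocytes and platelets was 1.68, with 6 of 7 genes at least 2-fold higher in macrophages. This value was known when the test was chosen. A rise in macrophages also cannot show that megakaryocytes were missing from the monocyte library, where Itga2b had 607 reads and Pf4 327. The test therefore cannot decide on this explanation. A smaller share of granulocytes of every stage in the macrophage library was tested on 9 late neutrophil genes of a separate list, 3 of which were higher and 4 lower, or 4 and 3 after centring (median -0.496, quartiles -2.26 and 1.81, percentile 17.7), which decides nothing. It may be that particular cells of the marrow were present in the monocyte preparation and lost in culture, or that precursors matured. Such cells include granulocyte and monocyte precursors, eosinophils, plasma cells and erythroid cells. For the granule, eosinophil and cell cycle genes these explanations cannot be told apart from a change within monocytes, without replicates or a purity value. Igha and Slc4a1, of the plasma cell and erythroid lists, had 6488 and 482 reads in the monocyte and 27 and 0 in the macrophage library. In those lists 6 of 8 and 8 of 9 genes were lower, and 2 and 0 were higher. Which cells gave the reads of those lists was not tested. Of the neutrophil and stromal lists, 5 of 18 and 3 of 10 genes were higher in the macrophage library, against 12 and 4 lower. Which cells expressed the higher ones was not tested.

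Ribosomal protein genes were lower in the macrophage library. A few genes that fill that library would lower all others by 1 factor, but the list median lay at -0.824 relative to the median of all genes, and the upper quartile of the list at -0.624. A bias against short transcripts or against their GC content was tested with random lists of genes matched to all 78 members. Matching used the deposited exon length of the gene and the GC content of its longest annotated transcript. These lists had a median of -0.314 and the lowest of 10000 was -0.833, against -1.06 for the ribosomal protein genes. Both measures can differ from those of the transcript expressed, so the test cannot exclude a bias against short transcripts or their GC content. Across genes the log2 ratio had a Spearman's rho of 0.053 with exon length and 0.055 with GC content. Reads shared with ribosomal protein pseudogenes were left out by the authors' counting, in numbers not known for either library, and were not tested. A biological difference between the cells stays open.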
